A study of Mus musculus with 6 samples.

How the data were processed

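Total RNA of wild-type mouse placenta at embryonic day 14, taken 4 h after the dam received PBS or LPS (50 µg/kg), was made into stranded total RNA libraries and sequenced on an Illumina HiSeq, per the labels' protocols. HISAT2, StringTie and the build GRCm38 are named in the submitters' processing notes without versions or roles. The program that counted reads, the annotation and the program that normalised the counts are not given in the sources used here.

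The authors deposited 1 table of 32956 gene symbols and 6 libraries. Its deposited values are a normalised signal, not whole counts: every value of a library is a multiple of what 1 read is worth there (0.854 to 1.34), and 100% of the values gave whole reads within a tolerance of 0.01. In all 6 libraries the median ratio to the geometric mean over libraries was 1.01292, which is what division by median-of-ratios size factors leaves. The recovered totals were 88192344 to 104949847 reads per library, so sampling noise is small for all but low genes. Replicate pairs differed by far more than sampling noise, with a chi-square per degree of freedom of 171 to 378, so no 2 libraries were counted as 1. That excess does not show whether the libraries came from separate placentas or dams. Small structural RNAs such as 7SL and 7SK took 30.6% to 35.4% of the reads. Some genes that most cells use, such as Supt16 and Ring1, are listed at 0 in LPS 1 only, so a 0 in the table may be a failed estimate. Genes with zeros are therefore given library by library, without a fold.

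A count test had been planned for raw counts. When the deposited values proved to be normalised, the main test became limma (version 3.58.1, R 4.3.3) with trend and robust empirical Bayes on log2(value + 2). It took genes at 10 or more in at least 3 libraries, with group as the sole term and Benjamini-Hochberg adjustment (threshold 0.05). This filter left 20285 genes. Limma, its pseudocount and its filter were thus chosen after the deposited values were seen, although whole reads could be recovered. The planned quasi-likelihood test of edgeR (version 4.0.16, TMM scaling) was run on the recovered reads and is given as an alternative. It tested 20328 genes and called 37 higher and 0 lower, against 66 higher and 1 lower by limma. Fold changes are LPS over PBS on the log2(value + 2) scale, and values are means ± SD of the normalised read counts.

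The samples were grouped by the labelled treatment. In total 30 gene lists (inflammatory pathways, stress and metabolic responses, and markers of placental, blood and immune cells), the list tests and the rule for named genes were fixed before the data were examined. The rule took the 14 largest increases and the 10 largest decreases among genes past the threshold, with no overlap between groups, a mean of at least 1 CPM and a symbol that is not provisional. To these it added 10 genes named in advance (Tnf, Il1b, Il6, Il10, Ptgs2, Ido1, Tph1, Slc38a2, Igf2 and Hmox1) and, from each list, the 4 members with the smallest p, or 6 in lists of 20 or more. No decrease qualified, since the single lower gene has a provisional symbol. Among the 14 increases, Acod1 and Mir5114 did not pass by edgeR (adjusted p = 0.0841 and 0.0689). Of the lists, 29 were tested as sets with camera at its preset correlation of 0.01 and with an estimated correlation, adjusted over the lists, and 11 were higher and 1 lower at the preset. With an estimated correlation 3 were higher, the cytokine, NF-kB and acute phase lists, and 0 lower. On the planned log2 CPM, camera at the preset also gave 11 higher and 1 lower. The fry test of whether a list's genes move on balance one way passed 7 lists, the cytokine, NF-kB, both interferon, acute phase, neutrophil and growth factor lists. The test for change in either direction passed 13, all of these but the growth factors and also the endothelial, prostaglandin, glucocorticoid, hypoxia, integrated stress, macrophage and decidual lists. Mean list scores per library were compared by exact two-sided permutation, whose smallest p is 0.1 for 3 against 3. In 9 lists all LPS scores lay on the same side of all PBS scores, above them in 8 (the 7 lists past fry and the endothelial list) and below in the chaperone list.

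Coordinates are those of GENCODE M21 on GRCm38, matched by symbol: 31834 symbols matched 1 gene, 81 matched more than 1 and 1041 none. The steps were tested on simulated data with the means and spread of these libraries, in which 50 genes each were changed 2-, 4-, 8- and 16-fold. In the simulated LPS against PBS comparison over 20285 genes, limma recovered 0% of the 2-fold, 48% of the 4-fold, 74% of the 8-fold and 70% of the 16-fold changes, with 13 false calls among 110. The edgeR test recovered 0%, 48%, 74% and 66%, with 14 false calls among 109. Both false shares lie above the nominal 5%.

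Alternatives were DESeq2 (version 1.42.0), edgeR with other size factors, no filter and a stricter one (at least 1 CPM in 3 libraries), and voom with quality weights. Another removed abundant RNAs (mitochondrial, globin, small structural and any listed ribosomal RNA) and scaled to the totals of the remaining reads. Further ones were each library left out, a block by replicate number, covariates for Y-linked and decidual genes, other thresholds and an edgeR test against 1.5-fold. DESeq2, edgeR and voom ran on the recovered reads, edgeR and voom with edgeR's own filter (20328 genes), so they changed more than 1 choice, as did the removal of abundant RNAs, which also changed the scaling from median-of-ratios factors to totals. Other pseudocounts (0.5 and 5), TMM scaling and removal of pseudogenes were added after the data were seen.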

Results

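RNA was measured in whole placenta of wild-type mice at embryonic day 14. Timed pregnant dams had received PBS, the vehicle, or 50 µg/kg of lipopolysaccharide (LPS), a bacterial cell wall component that activates innate immune receptors, and placentas were collected 4 h later. The series held 3 PBS and 3 LPS libraries of stranded total RNA. The recovered read totals were 88192344, 96266677 and 104949847 in PBS 1, 2 and 3, and 98634831, 97936084 and 97268961 in LPS 1, 2 and 3. The labels do not say whether libraries of a group came from separate dams or litters, or whether placentas were pooled. The p-values therefore measure only the spread between these samples, which may not be that between dams. The Y-linked gene Eif2s3y was listed at 1002 in PBS 1 and 1275 in LPS 2, at 10.3 in PBS 3 and at 0 in PBS 2, LPS 1 and LPS 3. Y-linked transcripts thus differed between libraries within both groups, so neither group consisted only of technical repeats of the same RNA. LPS 1 stood apart from the other 5 libraries. It held 11512 genes listed at 0 against 5969 to 7881 elsewhere, and it lay alone on the principal component that carried 38.4% of the variance. LPS 3 lay alone on the second component, with 19.1% of the variance, at 104.5 against -53.95 to -4.12 elsewhere. The voom quality weight was lowest in PBS 3, at 0.688, and next in LPS 1, at 0.704.

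The comparison of LPS with PBS asks which placental transcripts differ 4 h after the dam received LPS. Of 20285 genes tested, 66 were higher and 1 was lower in LPS by limma at an adjusted p under 0.05. All 67 differed by 2-fold or more with no overlap between the groups. Genes past this threshold would seldom overlap, so the lack of overlap is no separate support. Over all 20285 tested genes, 2924 had no overlap, where chance alone separates 10% of genes. At an unadjusted p under 0.05, limma had 833 genes higher and 672 lower. Inflammatory cytokines and chemokines led the increases. Of the 32 list members in the deposited values, 26 were tested. Over all genes 10 of these were past the threshold, and 21 when adjusted over the list alone. Csf3, the granulocyte colony-stimulating factor (chromosome 11, 98701263 to 98703629), rose 91.2-fold, from a normalised read count of 4.87 ± 1.32 to 641 ± 215 (SD, n = 3 per group; limma adjusted p = 0.00251). The neutrophil-attracting chemokines Cxcl2 (chromosome 5, 90903871 to 90905938) and Cxcl1 rose 27.4-fold, from 40.2 ± 10.5 to 1175 ± 383, and 12.1-fold, from 807 ± 332 to 9282 ± 510. Ccl4 (chromosome 11, 83662584 to 83664683) and Ccl3 (chromosome 11, 83647844 to 83649355), monocyte-attracting chemokines, rose 27.0-fold, from 109 ± 24.8 to 3120 ± 1387, and 16.4-fold, from 67.8 ± 31.4 to 1112 ± 364. Ccl20 was listed at 0 in all PBS libraries and at 307, 219 and 371 in LPS 1, 2 and 3. Cxcl5 was listed at 0, 0 and 0.86 in the PBS libraries and at 155, 313 and 447 in the LPS libraries. The limma adjusted p was 0.00286 for Ccl20 and 0.0105 for Cxcl5.

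Among the cytokines named in advance, Tnf (chromosome 17, 35199381 to 35202007) rose 11.9-fold, from 43.7 ± 13.5 to 525 ± 46.7 (limma adjusted p = 0.0105). Il6 (chromosome 5, 30013114 to 30019981) rose 8.75-fold, from 34.5 ± 6.44 to 316 ± 47.7 (limma adjusted p = 0.0113), and Il1b (chromosome 2, 129364570 to 129371139) rose 7.33-fold, from 119 ± 43.9 to 862 ± 223 (limma adjusted p = 0.0298). Il10, which encodes an anti-inflammatory cytokine, was listed at 0 in all PBS libraries and at 61.9, 23.1 and 16.1 in LPS 1, 2 and 3, and did not pass by limma (adjusted p = 0.212) or edgeR (adjusted p = 0.257) but did by DESeq2 (adjusted p = 4.75e-04). The median log2 fold change of the cytokine list was 3.0, or 2.82 without the 2 members listed at 0 in all PBS libraries. Its camera test gave an adjusted p of 2.23e-37, and an adjusted p = 0.00371 with an estimated correlation. All 3 LPS libraries had a higher mean score than all PBS libraries, at the smallest two-sided p that an exact permutation test of 3 against 3 allows, 0.1.

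**Figure D1:**
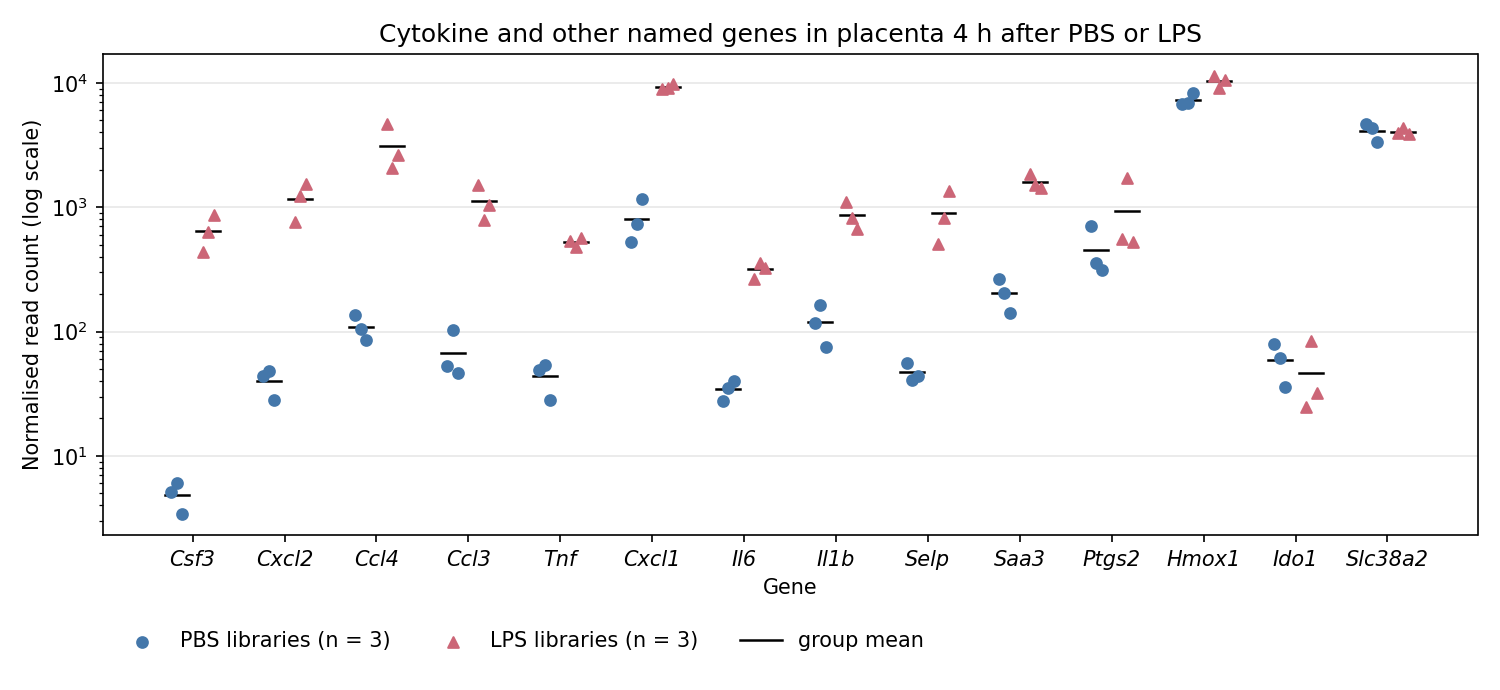
Normalised read counts (log scale) of 14 named genes in the 3 PBS libraries (circles) and the 3 LPS libraries (triangles), with bars at the group means. Csf3 lies between 3.44 and 6.05 in PBS and between 433 and 862 in LPS, while the groups overlap for Ptgs2, Ido1 and Slc38a2.

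Targets and feedback regulators of NF-kB, the transcription factor downstream of LPS receptors, had 6 of 24 members higher over all genes, 18 adjusted over the list alone and all 24 fold changes above 0. Nfkbia, the inhibitor that NF-kB induces against itself, rose 3.34-fold, from 1519 ± 176 to 5084 ± 628. Birc3 rose 6.44-fold, from 224 ± 91.1 to 1392 ± 200, and the LPS co-receptor gene Cd14 rose 3.23-fold, from 517 ± 66.6 to 1681 ± 275. The list's median log2 fold change was 1.2 (camera adjusted p = 6.01e-25; adjusted p = 0.0453 with an estimated correlation).

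Type I interferon response genes had 7 of 32 members higher over all genes and 25 adjusted over the list alone. Oasl1 rose 5.36-fold, from 122 ± 10.2 to 685 ± 226, and Stat1, the transcription factor of interferon signalling, rose 2.34-fold, from 1466 ± 158 to 3427 ± 225. Mx2 rose 4.33-fold, from 60.5 ± 8.05 to 267 ± 4.18; its transcript is 94.8% identical to that of Mx1 over 921 bases, so reads could have been split between them. The median log2 fold change was 1.17 (camera adjusted p = 1.50e-30), and the call was lost with an estimated correlation, at an adjusted p of 0.0851. Interferon gamma GTPases and antigen presentation genes had 5 of 27 members higher over all genes and 20 adjusted over the list alone. The interferon-induced GTPase genes Gbp5 (chromosome 3, 142493978 to 142522344) and Gbp2 rose 18.4-fold, from 35.6 ± 15.3 to 675 ± 258, and 4.08-fold, from 345 ± 120 to 1367 ± 139. The signalling inhibitor Socs1 rose 6.66-fold, from 40.9 ± 14.6 to 272 ± 29.7. The list's median was 1.23 (camera adjusted p = 5.79e-23; adjusted p = 0.0851 with an estimated correlation).

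Acute phase and STAT3 response genes had 3 of 22 members higher over all genes and 10 adjusted over the list alone. These were the serum amyloid gene Saa3, 8.02-fold higher (203 ± 61.4 to 1599 ± 227), the cytokine signalling inhibitor Socs3, 4.91-fold higher (646 ± 106 to 3205 ± 703), and haptoglobin, Hp, 2.96-fold higher (156 ± 11.2 to 467 ± 36.0). The median log2 fold change was 0.65, or 1.21 without PBS 2 and 1.16 without LPS 3 (camera adjusted p = 1.76e-12; adjusted p = 0.0453 with an estimated correlation). Beside these immune lists, marker lists of neutrophils and erythroid cells passed camera at its preset correlation. Neutrophil markers had a median log2 fold change of 0.48, or 0.31 without PBS 1 and 1.0 without LPS 3 (camera adjusted p = 1.50e-05; adjusted p = 0.0534 with an estimated correlation). In that list 1 of 17 members was higher over all genes and 5 adjusted over the list alone. The member past the threshold was Fpr2, a formyl peptide receptor (chromosome 17, 17887824 to 17893952), 12.4-fold higher (12.1 ± 5.70 to 163 ± 9.78). Ngp, a neutrophil granule gene, was at 4.99 ± 2.58 in PBS and 26.6 ± 4.36 in LPS (limma adjusted p = 0.408). Erythroid markers had a median of 0.69, or 1.11 without PBS 3, with 15 of 16 fold changes above 0. By limma 3 were higher at an unadjusted p under 0.05 and none was past the threshold over all genes, where edgeR and DESeq2 also had 0, or adjusted over the list alone. They had a camera adjusted p of 1.12e-04 that became an adjusted p of 0.414 with an estimated correlation. Globin transcripts took 2.50%, 3.03% and 4.96% of the reads in PBS 1, 2 and 3 and 5.0%, 4.43% and 3.58% in LPS 1, 2 and 3.

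Genes of endothelial activation and coagulation had 1 of 17 members higher over all genes and 4 adjusted over the list alone. Selp, which encodes the leukocyte adhesion receptor P-selectin (chromosome 1, 164115264 to 164150026), rose 17.1-fold, from 46.9 ± 8.24 to 892 ± 425 (limma adjusted p = 0.0138). The adhesion receptor genes Icam1, at 1631 ± 327 and 3958 ± 840, and Vcam1, at 185 ± 27.9 and 371 ± 79.1, passed by limma adjusted over the list alone, and over all genes by DESeq2 (adjusted p = 1.54e-04 and 0.0325) but not by limma (0.135 and 0.284) or edgeR (0.181 and 0.332). The median log2 fold change was 0.17 (camera adjusted p = 0.00147; adjusted p = 0.115 with an estimated correlation), 0.55 without LPS 1 and -0.023 when abundant RNAs were left out and the rest scaled to totals, steps that moved the median of all tested genes from -0.02 to -0.22. Madcam1, a ligand for lymphocyte integrins (chromosome 10, 79664559 to 79668537), rose 34.7-fold, from 18.2 ± 1.51 to 714 ± 196 (limma adjusted p = 0.00251). Acod1, whose enzyme makes itaconate in activated macrophages (chromosome 14, 103046977 to 103056573), rose 36.8-fold, from 15.4 ± 9.74 to 609 ± 323 (limma adjusted p = 0.0443), and 23.9-fold without PBS 3. The named increases also held 3 features whose reads are uncertain. Ldha-ps, a processed pseudogene 92.2% identical to Ldha, was listed at 0 in all PBS libraries and at 444, 553 and 397 in LPS 1, 2 and 3, while Ldha had a log2 fold change of 0.10 (limma adjusted p = 0.922). Rpl15-ps2, a processed pseudogene 98.7% identical to Rpl15, was 70.8-fold higher (37.6 ± 8.46 to 2822 ± 735), while Rpl15 had a log2 fold change of 0.42 (limma adjusted p = 0.853). Mir5114 (chromosome 19, 44303171 to 44303231) lies within Scd2 on the same strand and was 14.5-fold higher (7.43 ± 2.42 to 147 ± 87.9).

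In the prostaglandin and parturition list, 1 of 14 members was higher, over all genes and adjusted over the list alone. It was Hpgd, which encodes the enzyme that inactivates prostaglandins, 2.02-fold higher (1599 ± 124 to 3236 ± 301; limma adjusted p = 0.0482). Its call was lost by edgeR (adjusted p = 0.0689) and in all 6 fits without 1 library. Of 12 unblocked alternatives that kept all libraries, edgeR included, it passed in 5. Ptgs2, the inducible prostaglandin synthase, was at 457 ± 213 in PBS and 935 ± 679 in LPS (limma adjusted p = 0.782). The list's median was 0.02 (camera adjusted p = 0.492, but 0.0152 by DESeq2).

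The stress and hormone response lists had no member past the threshold over all genes by limma or edgeR, and of 102 members 15 were higher and 4 lower by limma at an unadjusted p under 0.05. DESeq2 called 5 higher, Pfkfb3, Nupr1, Ppp1r15a, Adm and Ddit4, and 1 lower, Herpud1. Targets of hypoxia-inducible factor had 2 of 21 members higher adjusted over the list alone, Pfkfb3 at 307 ± 83.3 and 838 ± 90.8 and Adm at 4556 ± 962 and 9154 ± 1394, with a median of 0.18, or 0.27 without LPS 3 and -0.017 when abundant RNAs were left out and the rest scaled to totals. Their camera adjusted p was 0.0332, and the adjusted p was 0.267 with an estimated correlation. It was also 0.0509 without PBS 2, 0.0896 without PBS 3, 0.106 without LPS 1, 0.119 without LPS 2 and 0.0512 with the stricter filter. Endoplasmic reticulum chaperones had 14 of 16 fold changes below 0, a median of -0.20, or -0.11 without PBS 1 and -0.32 without PBS 3, and no member past the threshold by limma adjusted over the list alone. Herpud1 was at 6522 ± 1488 and 3571 ± 569. The list was lower by camera (adjusted p = 0.0258) but not with an estimated correlation (adjusted p = 0.625), and its adjusted p was 0.152 without PBS 1, 0.105 without LPS 2, 0.0965 without LPS 3 and 0.0639 with no filter. Integrated stress response genes had 3 of 20 members higher adjusted over the list alone, Ppp1r15a, Nupr1 and Slc7a11, with a median of -0.05 and a mean of 0.18 (camera upward, adjusted p = 0.161, but 0.0144 by DESeq2). Glucocorticoid-induced genes had 1 of 14, Ddit4, with a median of 0.01 (camera adjusted p = 0.0973, 0.0305 without PBS 1, 0.0219 without PBS 2 and 0.0293 by DESeq2). Metallothionein and antioxidant genes had none of 14, with a median of 0.06 (camera adjusted p = 0.402). Their member Hmox1, encoding heme oxygenase, was at 7284 ± 865 and 10331 ± 1191 (limma adjusted p = 0.497). Complement genes had none of 17 and a median of 0.29. Their camera adjusted p was 0.0369, and the adjusted p was 0.427 with an estimated correlation, 0.320 without PBS 3, 0.198 without LPS 1, 0.119 without LPS 2 and 0.0591 to 0.0847 in 4 other settings.

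Placental metabolism and growth lists had no member past the threshold by limma, over all genes or adjusted over the list alone, and none by edgeR over all genes. Of 209 members 10 were higher and 1 lower by limma at an unadjusted p under 0.05, and DESeq2 called 4 higher, Rps27a, Igfbp1, mt-Co1 and mt-Th, and 0 lower. Tryptophan, kynurenine and serotonin genes had a median of -0.08 and a mean of 0.10 over 16 members (camera upward, adjusted p = 0.810). Ido1, which breaks down tryptophan, was at 58.7 ± 21.4 and 46.8 ± 32.2 (limma adjusted p = 0.889), and Tph1, which starts serotonin synthesis, was listed at 0, 61.4 and 9.45 in PBS and at 8.53, 61.5 and 25.4 in LPS (limma adjusted p = 0.876). Nutrient transporters had a median of 0.07 over 24 members (camera adjusted p = 0.941), and the amino acid transporter gene Slc38a2 was at 4114 ± 712 and 4052 ± 237 (limma adjusted p = 0.995). Angiogenic and insulin-like growth factors had a median of 0.08 over 22 members and a mean of 0.28. They did not pass camera (adjusted p = 0.135) but passed fry, which does not compare a list with other genes (adjusted p = 0.0132), and all LPS libraries had a higher mean score than all PBS libraries (exact two-sided permutation p = 0.1, the smallest possible). Igf2 was at 5270 ± 4344 and 8446 ± 4018 (limma adjusted p = 0.842). Cell cycle genes had a median of -0.03 over 35 members (camera adjusted p = 0.986, but 0.0331 without PBS 1, as lower, and 8.00e-04 without PBS 3, as higher). Ribosomal protein genes had 74 of 83 fold changes above 0 and a median of 0.21, which was 0.13 without PBS 2, 0.34 without PBS 3, 0.43 without LPS 2 and 0.024 without LPS 3 (camera adjusted p = 3.30e-05, 0.216 without LPS 3; adjusted p = 0.680 with an estimated correlation). Mitochondrially encoded genes had a median of 0.08 and a mean of -0.01 over 31 members (camera upward, adjusted p = 0.169, but 0.0333 by DESeq2 and 0.0439 with no filter).

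Marker lists of placental and maternal cell types had no member past the threshold over all genes by limma or edgeR, and of 128 members 5 were higher and 2 lower by limma at an unadjusted p under 0.05. DESeq2 called Lyve1, a macrophage marker, higher and Pgr lower. Macrophage and monocyte markers had a median of 0.27 over 15 members, or 0.13 without PBS 3 and 0.18 without LPS 1 (camera adjusted p = 0.141, but 0.0106 with the stricter filter). Uterine natural killer and lymphocyte markers had a median of -0.27 over 14 members, or -0.12, -0.49 and -0.092 without PBS 1, 2 and 3 and -0.072 without LPS 3 (camera adjusted p = 0.359, 0.0190 without PBS 2). Decidual stroma markers had a median of 0.04 over 15 members (camera adjusted p = 0.802). The progesterone receptor gene Pgr, at 470 ± 108 and 210 ± 21.3, was lower by limma adjusted over the list alone. Junctional zone trophoblast markers had a median of 0.07 over 23 members (camera adjusted p = 0.187, 0.0142 without LPS 2). Trophoblast giant cell markers had a median of 0.31 over 14 members, or 0.13 without PBS 2 and 0.11 without LPS 3 (camera adjusted p = 0.158, 0.0101 without LPS 2 and 0.0411 by DESeq2). Labyrinth trophoblast markers had a median of -0.04 and a mean of -0.06 over 18 members (camera upward, adjusted p = 0.986). Fetal endothelial markers had a median of 0.07 over 16 members (camera adjusted p = 0.635). Yolk sac endoderm markers had a median of 0.05 over 13 members (camera adjusted p = 0.810, 0.0235 without PBS 2 and 0.0258 without LPS 3), and their mean score varied within groups by an SD of 2.05 in PBS and 1.96 in LPS. Of the Y-linked list only Eif2s3y passed the filter on low values, so it had no set test.

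**Figure D2:**
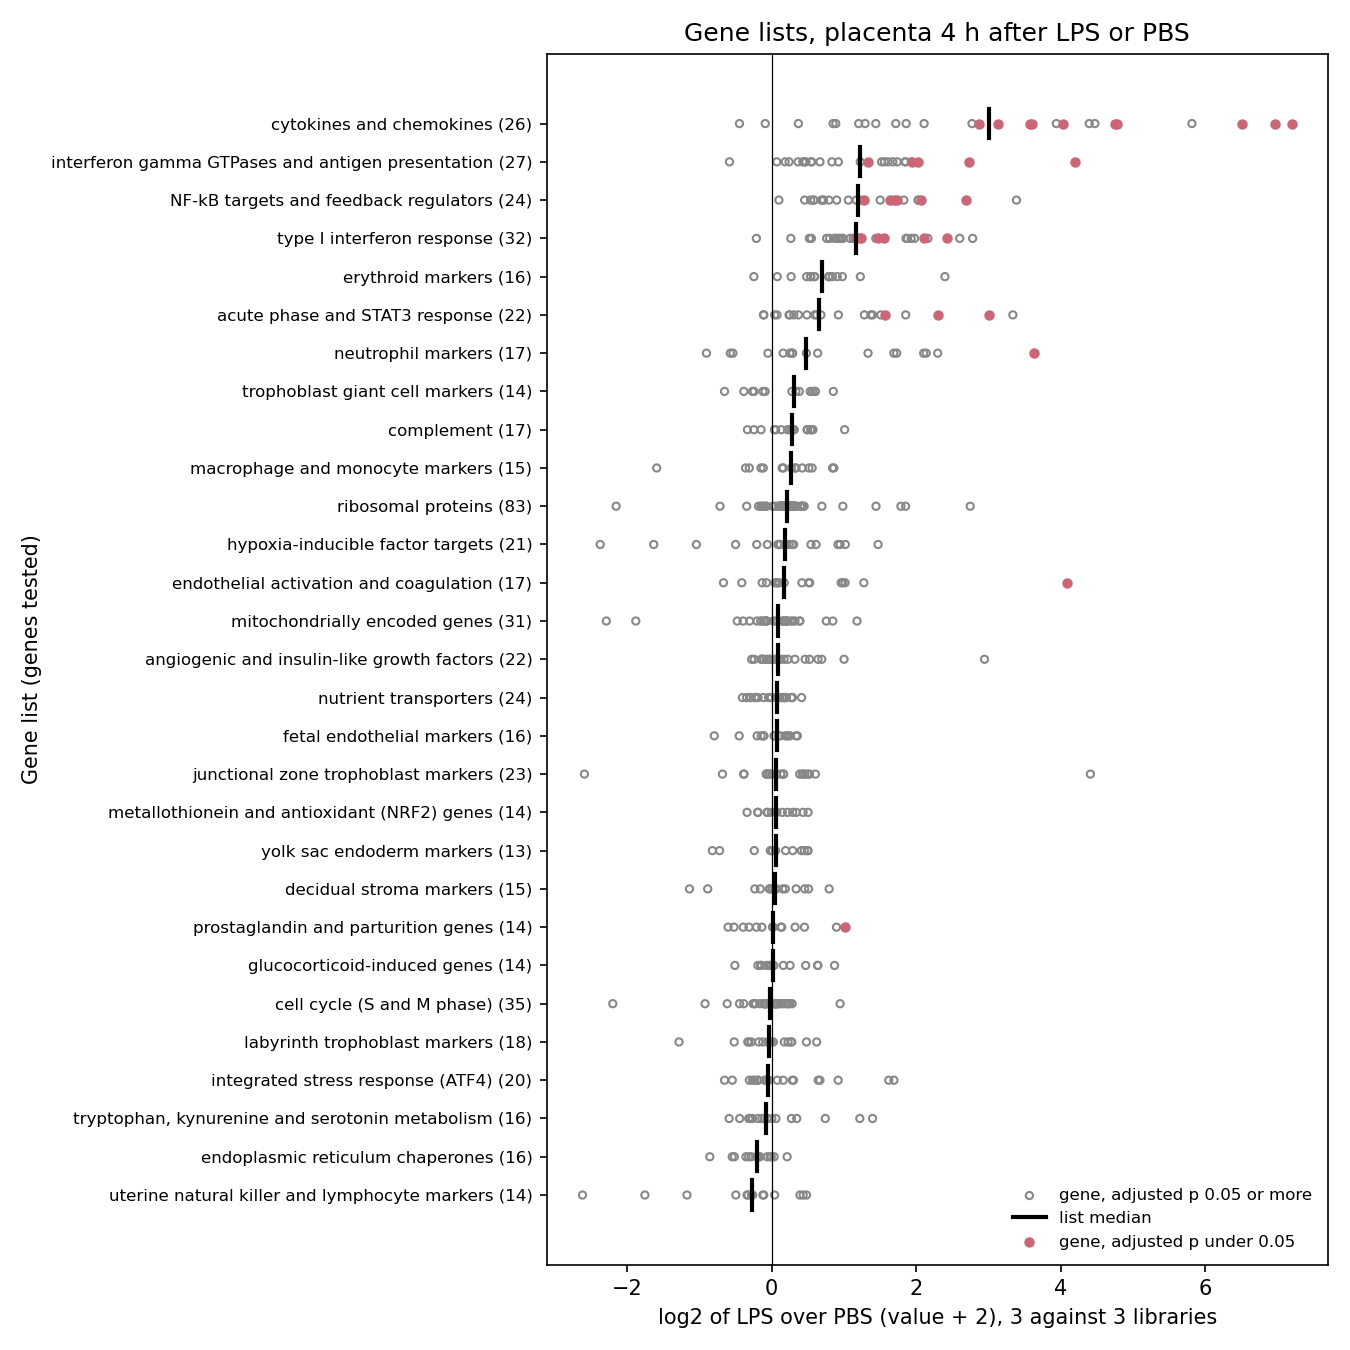
Log2 of LPS over PBS (value + 2) of each tested member of the 29 lists with a set test, ordered by the list median (black bar), with genes at an adjusted p under 0.05 filled and the others open. Cytokines and chemokines have the highest median, 3.0, and the filled genes all lie to the right of 0.

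Genes were tested by limma on log2(value + 2), so fold changes of low genes are understated. The count of higher genes fell from 66 to 27, 15 and 16 without PBS 1, 2 and 3 and to 15, 5 and 12 without LPS 1, 2 and 3. Of the 67 genes, 24, 14, 14, 15, 5 and 12 in the same order remained past the threshold, and only Ccl4, Csf3, Madcam1, Ldha-ps and Rpl15-ps2 did so in all 6 of these fits. By edgeR on the recovered reads 37 genes were higher and 0 lower, all 37 among the limma calls, with 773 higher and 554 lower at an unadjusted p under 0.05. Of the genes named above as higher, Il1b, Birc3, Socs1, Gbp2, Acod1, Mir5114 and Hpgd did not pass by edgeR, with adjusted p values of 0.0519 to 0.0841, and Mx2, Cd14, Hp, Stat1, Fpr2, Il1b, Socs1, Acod1, Mir5114 and Hpgd passed in 0 of the 6 fits. DESeq2 on the same reads gave 276 higher and 92 lower.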

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

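The limma main test, limma with TMM scaling, other pseudocounts for genes and the removal of pseudogenes were chosen after seeing the data. The edgeR quasi-likelihood test with TMM was the planned one, run here on the recovered reads. The 66 higher genes became 276 by DESeq2, 41, 36 and 37 by edgeR with RLE, upper-quartile and TMM factors, 29 with abundant RNAs left out, 28 and 30 with the Y-linked and decidual covariates, 17 by glmTreat and 7 at an adjusted p under 0.01. The single lower gene, Gm9126, became 92 lower genes by DESeq2, 0 by all 3 edgeR fits, by glmTreat, with the stricter filter and at 0.01, 2 with no filter, 3 with abundant RNAs left out, 4 without pseudogenes, 5 at a pseudocount of 5 and 9 at an adjusted p under 0.1. The smaller number of libraries is the construction of the left-out fits, which gave 5 to 27 higher and 0 to 3 lower genes, and 9 to 12 higher and 0 to 2 lower lists. The 12 lists past camera became 3 higher and 0 lower with an estimated correlation, and the lower list was lost (0) with no filter. DESeq2 gave 16 higher lists, adding the prostaglandin, glucocorticoid, integrated stress, giant cell and mitochondrial lists. The mitochondrial list also passed with no filter, and the macrophage list with the stricter one. Apart from the estimated correlation, complement lost its call in 4 settings and hypoxia in 2, the stricter filter and the block. Leaving out abundant RNAs and scaling to the remaining totals, which were not tried apart, moved the median log2 fold change of all tested genes from -0.02 to -0.22, and list medians moved with it. With replicate numbers as a block, 2 genes were higher by limma and 1 by edgeR. Same-numbered libraries had correlations of deviations of -0.04, 0.07 and 0.03, and 3 of 6 libraries matched their own number best. This gave no clear sign that the numbers pair the samples, but with 3 libraries per group it cannot exclude pairing. Outside the fits without 1 library, single genes kept their direction and side of the threshold in 1103 cases, lost the call in 248 and gained it in 28, with 0 reversed, and lists did so in 414, 16 and 6 cases, with 27 medians reversed, 1 of them in a list that gained its call. Beyond the fewer samples of the left-out fits, the cause was not tested.

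Medians near 0 changed sign. Glucocorticoid-induced genes went to -0.0083 by DESeq2, -0.0080 by edgeR with RLE, -0.043 with upper-quartile, -0.018 with TMM and with camera on edgeR z-scores, -0.094 by voom and -0.18 with abundant RNAs left out. The last setting also gave -0.023 for endothelial activation, -0.17 for prostaglandin, -0.017 for hypoxia, -0.13 for metallothionein, -0.12 for transporters, -0.11 for growth factors, -0.15 for decidual stroma, -0.13 for junctional zone, -0.13 for fetal endothelial and -0.11 for yolk sac lists. Voom gave 0.033 for integrated stress, -0.051 for transporters, 0.14 for cell cycle and -0.028 for junctional zone. The stricter filter gave 0.020 for integrated stress and 0.0036 for cell cycle, DESeq2 gave 0.011 for labyrinth, upper-quartile factors gave -0.011 for yolk sac, and the edgeR block gave 0.010 for cell cycle and -0.030 for yolk sac. Without 1 library each, medians ranged from -0.74 to 1.33 for yolk sac, -0.0080 to 0.21 for integrated stress, -0.0082 to 0.12 for metallothionein, -0.018 to 0.14 for decidual stroma, -0.020 to 0.14 for fetal endothelial, -0.13 to 0.18 for glucocorticoid, -0.069 to 0.090 for transporters, -0.23 to 0.33 for cell cycle, -0.17 to 0.15 for labyrinth, -0.062 to 0.14 for mitochondrial, -0.30 to 0.13 for tryptophan and -0.069 to 0.24 for junctional zone lists. For Slc38a2 the range was -0.16 to 0.095. The fitted log2 difference of Tph1, which is listed at 0 in PBS 1 and so has no fold, ranged from -0.031 to 2.46, with the negative value without PBS 1. Without a change of sign, medians ranged from 0.0082 to 0.096 for prostaglandin and 0.063 to 0.14 for growth factor lists. The cause was not tested for any of these. The cytokine, NF-kB, both interferon, acute phase, endothelial, neutrophil and erythroid lists passed camera at the preset correlation in all 6 left-out fits, but with an estimated correlation and all libraries only the cytokine, NF-kB and acute phase lists passed. With 3 libraries per group and the spread of these libraries, the simulated tests found no 2-fold change, so changes of that size would mostly be missed. In the real data limma did call some genes near 2-fold, such as Hpgd at 2.02 and Rcan1 at 2.06.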

Other observations

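Of the 67 genes past the threshold, 33 belonged to no list, and those named here were chosen after their values were seen. Cd274, which encodes the T-cell inhibitor PD-L1, rose 8.30-fold, from 119 ± 33.5 to 981 ± 104 (SD, n = 3; limma adjusted p = 0.0105). Adora2b, an adenosine receptor gene, rose 4.58-fold, from 315 ± 31.9 to 1456 ± 238, and Socs2, an inhibitor of cytokine and growth hormone signalling, rose 3.01-fold, from 239 ± 49.4 to 711 ± 8.99. Trim21, the cytosolic antibody receptor, rose 4.51-fold, and Nod2, a sensor of bacterial wall peptides, 3.81-fold. Casp4, the caspase that binds LPS in the cytosol, rose 2.79-fold, and Eif2ak2, the kinase activated by double-stranded RNA, 2.70-fold. Ifnb1, which encodes interferon beta, was listed at 0 in all PBS libraries and at 72.5, 99.1 and 76.3 in LPS 1, 2 and 3 (limma adjusted p = 0.0205).

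Adamts4, a protease gene for matrix proteoglycans, rose 2.61-fold, from 490 ± 83.1 to 1272 ± 140, and Tgm1, a transglutaminase gene, rose 2.50-fold, from 1649 ± 61.3 to 4146 ± 549. Rcan1, an inhibitor of calcineurin, rose 2.06-fold, from 2171 ± 129 to 4461 ± 81.6, and the transcription factor gene Junb rose 3.20-fold, from 1766 ± 246 to 5640 ± 546. These genes had limma adjusted p values of 0.0450, 0.0248, 0.0271 and 0.0147. Of the 12 genes named here, Socs2, Nod2, Casp4, Eif2ak2, Ifnb1, Adamts4, Tgm1 and Rcan1 passed in 0 of the 6 fits without 1 library, Trim21 and Junb in 1, Adora2b in 3 and Cd274 in 4. By edgeR, Socs2, Nod2, Eif2ak2, Ifnb1 and Adamts4 did not pass, with adjusted p values of 0.0501 to 0.0599.

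The tests below were chosen after the results were seen, except the splits of the lists and the identity of the pseudogenes. For the immune genes, the splits were counted over all genes, and the real split called 67, which include 7 pseudogenes (the lower gene Gm9126 among them), against at most 5 in the other splits (1 of 10 splits as large). For the lists the real split called 12 and the others 4 to 13, so 2 of 10 splits were as large, whereas with an estimated correlation the real split called 3 lists and the others 0. Every other split mixed both groups and kept part of the LPS difference, with a cytokine median of 0.83 to 1.25 in size against 3.0. The other splits are therefore not free of the LPS effect. With 10 splits no share under 0.05 can be reached. A larger share of macrophages and monocytes in an unchanged state is argued against as the whole of the rise. Their markers had a median log2 fold change of 0.27 (SD 0.60 over 15 genes, 0.13 to 0.30 without 1 library) against 3.0 for the cytokines (2.94 to 3.27). The markers moved both ways, from -1.59 (Cx3cr1) to 0.86 (Fcgr1). Their means without LPS ran from 16.5 (Itgam) to 13068 (Cd68). With markers already this high, the median cannot tell a small influx of activated cells from induction in resident cells. Neutrophils brought in by LPS cannot be told apart from induction in resident cells, because 5 neutrophil granule and receptor genes, most near the floor, had a median of 0.64 (SD 0.75), with Ngp at 2.10 and Csf3r at 0.28, and S100a8 was already at 20799 ± 3905 without LPS.

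Several pseudogenes were past the threshold, and Psg16, a pregnancy-specific glycoprotein gene, missed it by limma without overlap between the groups. None of the 7 called genes that GENCODE marks as pseudogenes lay within 5000 bases of another called gene (0 of 7). Genes that missed the threshold were not searched, so an induced neighbour that was not called is not excluded. In 6 of 7 an aligned part of the transcript is over 90% identical to another gene with a mean of 10 or more, but that part is 37.2% of the transcript for Mx2 and 61.9% for Gm5987, whose match is the pseudogene Ldha-ps, and reads assigned to either copy remain a candidate explanation, as does a change of the pseudogenes themselves. Psg16 was at 206166, 142839 and 41763 in PBS and 2566, 2339 and 711 in LPS (limma adjusted p = 0.0549; past the threshold in 4 of 12 unblocked alternatives that kept all libraries, DESeq2 among them with an adjusted p of 6.22e-21), while Psg23 was at 64.4, 65537 and 96252 in PBS and 157827, 167359 and 152634 in LPS, and their sum had a log2 fold change of -0.17 (largest SD within a group 0.34). Over their longest alignment, 1318 bases of the Psg16 transcript of 4421, Psg16 and Psg23 are 79.6% identical. That is no more than Psg16 and the 10 other aligned Psg genes (79.6% to 81.4%). It argues against misaligned reads in that part, while identity in the rest of the transcript was not assessed. Of these genes only Psg23 shares an older name, Cea11, with Psg16. Entry of the same reads under either name may therefore be involved, and a real switch between the genes was not excluded.

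LPS 1 listed 21 genes at 2 or less that were at 200 or more in all other libraries, against 0 to 5 such genes in each of the other libraries. Its total of 98634831 reads was not low, which argues against shallow sequencing. Of the 11 genes with an overlapping gene, 9 had a sum with all overlapping genes that was still lower in LPS 1 than in every other library, which argues against reads passed to an overlapping gene for most of these, and the other 10 genes had none in the annotation. What removed these genes stays open, and without LPS 1 the counts were 15 higher and 3 lower genes.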
